A study of Macaca mulatta with 39 samples.

How the data were processed

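Messenger RNA was measured in 39 samples of cultured rhesus macaque cells, each on a single-colour oligonucleotide array. The samples came from 13 cell sources with 3 arrays each: 2 embryonic stem cell (ESC) lines, 8 cultures of fibroblasts grown from teratomas, and 3 cultures of skin fibroblasts. The labels call the arrays of a source biological triplicates. Per the labels' protocols, total RNA was extracted with Trizol, purified on RNeasy columns and checked on a Nanodrop and a Bioanalyzer. The labels also state that double-stranded cDNA was made with a T7 oligo(dT) primer and copied into biotin-labelled RNA by in vitro transcription. How the cells were grown, and how the arrays were hybridised and scanned, is not given in the sources used here.

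The deposited values are log2 signals, 1 per probe set and array. Per the labels' processing notes they were made with GCOS and RMA. RMA corrects background, makes the arrays' distributions alike and summarises the probes of a set. The versions and settings of both programs are not given in the sources used here. The log2 scale was checked on the values, which ran from 2.11 to 14.18 with no missing value. Array medians ran from 6.25 to 6.48. No depth applies to arrays, and the number of arrays and of sources limits the precision.

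The table held 52865 probe sets, of which 158 were controls and 674 were viral. Gene names came from the platform's probe annotation table, which names a single gene for 24969 probe sets, several genes for 361 and none for 27535. Probe sets with 1 gene name, without controls, came to 24956 and covered 14132 genes. The 6375 genes with more than 1 probe set were represented by the probe set with the highest mean over all arrays. Chromosomes were looked up by gene identifier in a RefSeq gene table of the assembly T2T-MMU8v2.0 for 13945 of the genes. No coordinates were used. Rhesus chromosomes 20 and 16 correspond to human 16 and 17, and rhesus 19 and X to human 19 and X.

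The unit of comparison was the source, so the 3 arrays of each source were averaged. The 13 means were fitted with limma 3.58.1 in R 4.3.3, with 5 classes (each ESC line, the teratoma fibroblasts of each line, and skin fibroblasts), which left 8 residual degrees of freedom. Each ESC line formed its own class, so the spread behind each test came from the teratoma and skin cultures, and the ESC sources were assumed to vary like them. A gene was called when its Benjamini-Hochberg adjusted p over all genes was under 0.05 and its log2 difference was at least 1 in size. Tests were two-sided. Contrasts compared the mean of both ESC lines with the mean of both teratoma classes, the mean of both ESC lines with skin, and the mean of both teratoma classes with skin. Further contrasts compared the teratoma fibroblasts of the lines, and asked whether the difference between ESCs and teratoma fibroblasts differed between the lines (the interaction). Differences between the 2 ESC lines, among teratoma cultures of a line (an F test) and among skin cultures (an F test) were tested in limma on all 39 arrays with the 13 sources as groups. These tests have 26 residual degrees of freedom and measure the spread between arrays of a source only.

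Genes called in one direction against both fibroblast kinds were tested for their place on each rhesus chromosome with Fisher's exact test, adjusted over the chromosomes. The genes called higher were also set beside 10000 random gene sets matched on mean expression. No matched sets were drawn for the genes called lower. Since both comparisons share the ESC sources, 100 simulations in which no class differed, fibroblasts included, gave the correlation that sharing alone produces. They also gave the number of genes called in both by noise alone, with all sources, ESCs among them, given the spread of the fibroblast cultures. A total of 24 gene lists were written, and 23 had the 3 measured genes needed for limma's camera test with a preset correlation of 0.01. Camera with an estimated correlation and fry were also run. The lists covered core pluripotency, fibroblast matrix, epithelial adhesion, cell cycle, chromatin and DNA methylation, activin, nodal, FGF and WNT signalling, MHC class I and interferon, senescence and stress, HOX genes, limb and skin position, imprinted genes, and Y-linked genes with XIST. The remaining lists marked smooth muscle, skeletal muscle, neural cells, endoderm, early mesoderm, trophoblast, keratinocytes, melanocytes, macrophages and leukocytes, endothelium, cartilage and bone, and adipocytes. The lists held 401 measured genes, 9 of them in more than 1 list.

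The genes named in the text were chosen by rule: for each main comparison, the 10 called genes with the largest rise and the 10 with the largest fall among genes whose source means did not overlap between the 2 cell types. For line comparisons and the interaction the rule took the 5 largest each way, for each list up to 4 members with the largest difference, and for a chromosome the 5 genes with the largest rise in both comparisons. POU5F1, NANOG, SOX2, LIN28A, DNMT3B, COL1A1, COL1A2, XIST and Y-linked genes were always included where measured. The comparisons, tests, thresholds, lists, naming rule and most alternatives were chosen before the data were examined. Genes named outside the rule are marked as chosen after their values were seen.

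Alternatives covered the unit of replication, the replicate letter as a block, line as a factor, quantile normalisation and median centring, other probe sets of a gene, removal of dim genes, the fold limit, the p threshold, a limma variance model with trend and robust settings, and leaving out each source or array in turn. Results without the 3 arrays whose profile lay nearer to another source than to their own, without the array with the widest actin gap, without all of these, and with no replicate letter were added after the data were seen. So was the rule that marks an array as out of place, an earlier form of which also marked TC38b and TD31c. All arrays were kept under their labels in every main result. The limma fits were tested on simulated data with known changes: between ESCs and teratoma fibroblasts, 85% of genes changed by 1.5 log2 units and 98% of genes changed by 3 were called, and 1.61% of calls were unchanged genes. The same figures were 79%, 97% and 4.35% between ESCs and skin, and 88%, 99% and 0.532% between teratoma and skin fibroblasts. Simulated ESC sources were given the spread of the fibroblast cultures, so the ESC figures hold only if ESCs vary like them. In the array-level test of the ESC lines, sources that differed only by the spread among fibroblast cultures gave 365 called genes. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probe sets with no gene name or several, controls and viral probe sets were left out of the gene tests, and unnamed and viral sets were tested apart.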

Results

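Gene expression was measured in pluripotent and differentiated cells of rhesus macaques that share a pedigree. ESCs, which come from early embryos and can form all cell types of the body, were represented by the male line C3106 and the female line C3806. Teratoma fibroblasts were grown out of teratomas, the mixed-tissue tumours that ESCs form when injected into immune-deficient mice. The male line gave 5 teratoma cultures (TA31 to TE31) and the female line gave 3 (TA38 to TC38). Skin fibroblasts came from animals that were parents of the lines (cultures M032, M088 and M106p1), and which animal was the parent of which line is not given in the sources used here. Each source had 3 arrays, and array medians lay between 6.25 and 6.48 on the log2 scale.

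The profiles of 3 arrays went against their labels. The array labelled C3806c had a POU5F1 signal of 4.84, while the other 5 ESC arrays lay between 12.67 and 13.17, and its LUM signal of 12.56 was at the fibroblast level. The array labelled M106p1f had an MYH3 signal of 11.61 against 6.83 and 6.75 in the other arrays of that skin culture. The array labelled TB31c had an MYH3 signal of 7.03 against 12.25 and 12.12 in its culture. All 3 arrays stay under their labels in the values that follow, and the gene counts are also given without them. The array labelled C3806a had a gap of 3.89 log2 units between 3′ and 5′ actin probe sets, a gap that widens where RNA or cDNA is shortened, against at most 0.78 in the other arrays. The median of this gap was 0.67 in ESC arrays, 0.27 in skin and 0.175 in teratoma arrays, while for GAPDH the medians were 0.59, 0.71 and 0.66. Without C3806a 515 genes rose and 791 fell against teratoma fibroblasts (642 and 920 with it), while without the array labelled C3806c 937 rose and 1168 fell. Leaving out C3806a gives C3806c more weight in the mean of its line, so the lower counts do not show an effect of the gap. Whether the gaps of the other ESC arrays bear on the differences was not tested. Many genes have more than 1 probe set, and the brightest is used. Of 69 genes picked for naming that were called against teratoma fibroblasts and have another, the brightest other probe set passed the fold limit in the same direction for 38, stayed under it for 27 and went the other way for 4. Against skin these were 52, 23 and 7 of 82 genes.

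**Figure D1:**
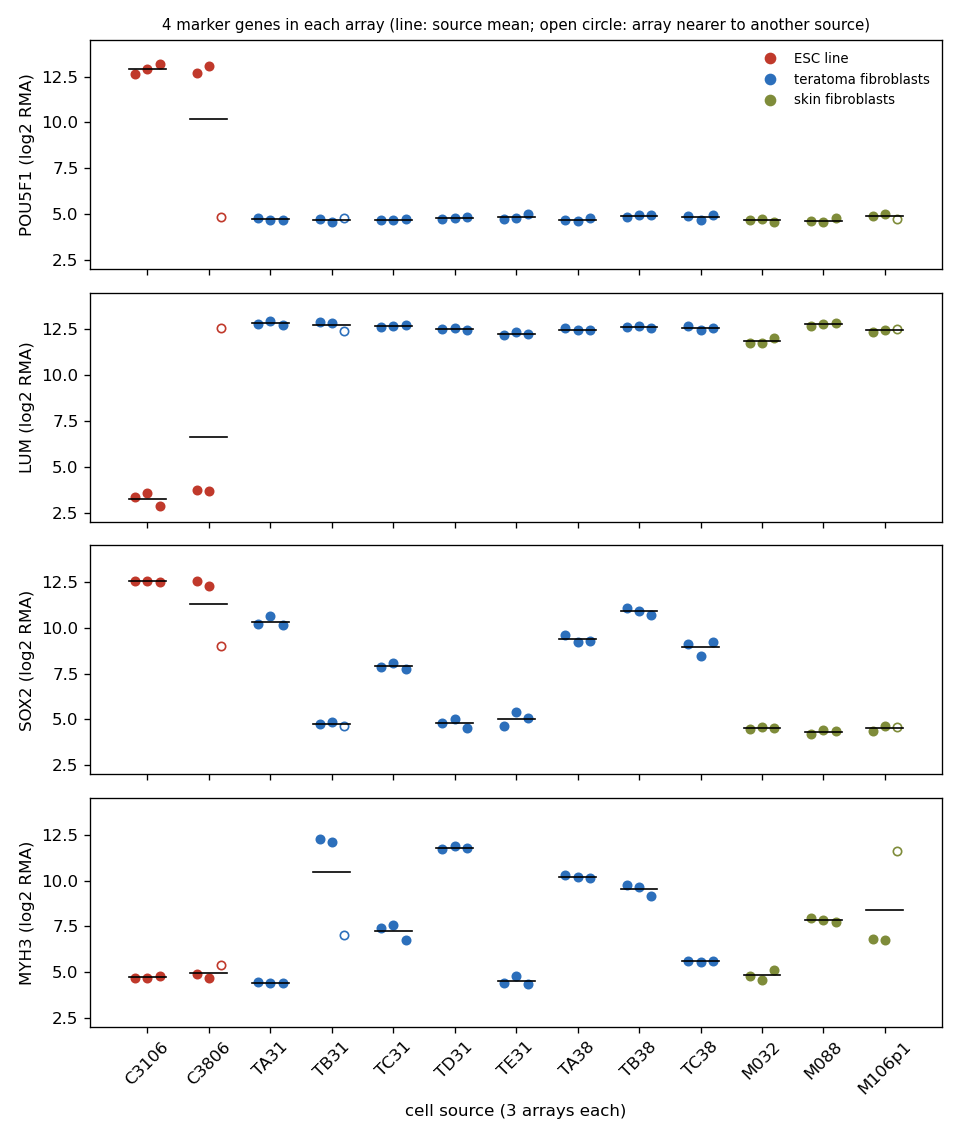
Log2 signals of POU5F1, LUM, SOX2 and MYH3 on the 39 arrays, each point an array, grouped by cell source, with lines at source means and open circles for the 3 arrays that went against their labels. The array labelled C3806c lay among the fibroblasts for POU5F1, at 4.84, while the other ESC arrays lay at 12.67 or above.

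The comparison of ESCs with teratoma fibroblasts asked which genes set pluripotent cells apart from differentiated cells of the same genome. Factors that keep cells pluripotent and proteins that bind epithelial cells together were among the largest rises in ESCs, and matrix proteins were among the largest falls. POU5F1, which encodes the central transcription factor of pluripotency (probe set MmuSTS.2285.1.S1_at, chromosome 4), had a log2 signal of 11.57 ± 1.93 (SD, n = 2 lines) in ESCs and 4.76 ± 0.08 (n = 8 cultures) in teratoma fibroblasts. It rose by 6.79 log2 units (SE 0.08, limma adjusted p = 1.32e-11), and by 8.14 without the 3 arrays. EPCAM, which encodes an epithelial adhesion protein (MmuSTS.2870.1.S1_at, chromosome 13), lay at 9.77 ± 1.69 against 2.84 ± 0.10 and rose by 6.91 (SE 0.07, adjusted p = 5.1e-12). Large rises also came from CTSV, a lysosomal protease, at 5.99, LIN28B, which blocks let-7 microRNA processing, at 5.49 (0.73 on another probe set), and DPPA4, a chromatin protein of early embryos, at 5.01. NFE2L3, a stress-response transcription factor, rose by 4.90, CLDN6, a tight-junction protein, by 4.87, CHGB, a secretory granule protein, by 4.84, NELL2, a secreted neural ligand, by 4.73, and BEND4, which carries a DNA-binding BEN domain, by 4.68. Over these genes the limma adjusted p ran up to 0.000478, for NFE2L3. All of these rises were larger without the 3 arrays, from 5.60 for BEND4 to 8.36 for EPCAM. In the teratoma cultures EPCAM lay between 2.76 and 3.06 and CHGB between 3.39 and 3.61, near background, which limits the size of such rises.

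Among the falls, LUM, which encodes the collagen-binding proteoglycan lumican (chromosome 11), had a signal of 4.94 ± 2.42 (n = 2) in ESCs and 12.59 ± 0.17 (n = 8) in teratoma fibroblasts, and fell by 7.64 (SE 0.21, limma adjusted p = 4.85e-09). It lay between 2.83 and 3.71 in the other 5 ESC arrays, with 2.11 the lowest value of any probe set, and background limits the size of such falls. FAP, a surface protease of activated fibroblasts, fell by 6.58, as did IFI16, a nuclear DNA sensor. EFEMP1, a fibulin of elastic tissue, fell by 6.44, SRGN, a granule proteoglycan, by 6.37, CCDC80, a matrix protein, by 6.12, and ASPN, a relative of lumican, by 6.08. The secreted WNT inhibitor DKK1 fell by 6.04, the decoy receptor TNFRSF11B by 6.0 and the cytokine IL6 by 5.83, with the highest adjusted p of these genes at 0.000719, for SRGN. All of these falls were larger without the 3 arrays, from 6.65 for IL6 to 9.13 for LUM. By the naming rule, these rises and falls were chosen from genes whose ESC line means both lay outside the range of the 8 teratoma means. NANOG, a core pluripotency factor, went the other way on its only probe set (MmugDNA.16220.1.S1_at, chromosome 11), with 8.63 ± 0.30 in ESCs and 9.67 ± 0.13 in teratoma fibroblasts, and fell by 1.04 (SE 0.11, adjusted p = 7.7e-05). SOX2, another core factor, lay at 11.91 ± 0.89 in ESCs and 7.75 ± 2.56 in teratoma fibroblasts and rose by 3.77 (SE 1.31, adjusted p = 0.0487). LIN28A and XIST were not measured. In limma, 642 genes rose and 920 fell, and without the 3 arrays the counts were 887 and 1156. Each ESC line was 1 source, so these tests rest on the spread among fibroblast cultures and do not carry the spread between ESC lines or arrays.

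**Figure D2:**
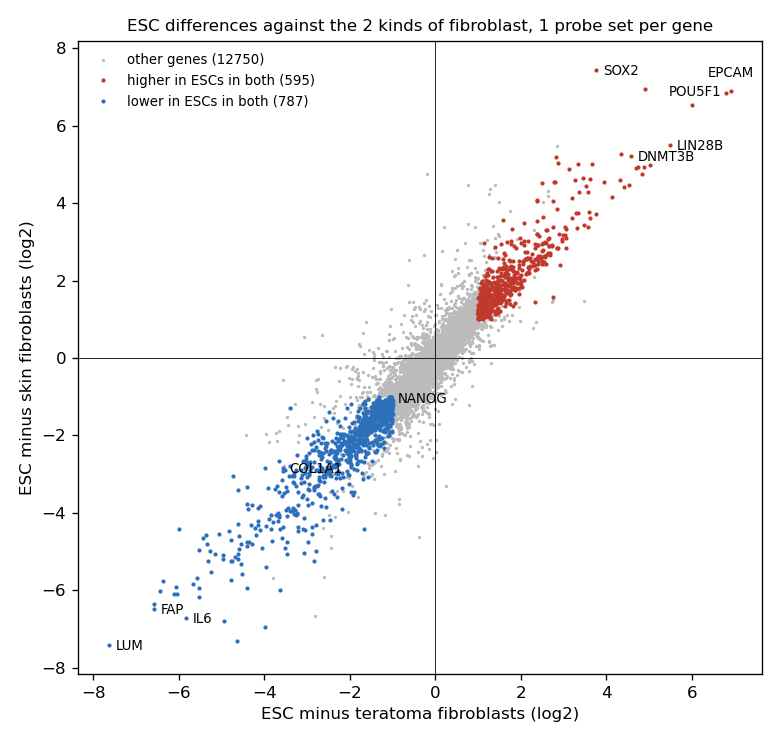
Log2 difference of ESCs minus teratoma fibroblasts (horizontal) against ESCs minus skin fibroblasts (vertical) for the genes tested, each point a gene. POU5F1 (6.79 and 6.84) and EPCAM (6.91 in both) lay at the upper right and LUM (−7.64 and −7.42) at the lower left.

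Of the fixed lists, 4 rose and 4 fell by camera between ESCs and teratoma fibroblasts, and 2 of them also passed with an estimated correlation. Of 20 core pluripotency genes 9 rose, among them PRDM14, a transcriptional repressor found in germline and pluripotent cells, by 4.13, and SALL4, a zinc-finger factor, by 2.97. NANOG, KLF4 and the WNT modulator SFRP2 fell (KLF4 by 2.64, SFRP2 by 2.28) (counts adjusted over the list alone 9 higher and 3 lower, camera adjusted p = 1.18e-05, adjusted p = 0.121 with an estimated correlation). Chromatin genes rose in 10 of 31 cases and fell in 1 (the same adjusted over the list alone), led by the DNA methyltransferase DNMT3B at 4.57, the demethylating enzyme TET1 at 3.62, the remodeller CHD7 at 2.76 and JARID2, a Polycomb partner, at 2.65, while TET2 fell by 1.29 (camera adjusted p = 7.26e-08, adjusted p = 0.121 with an estimated correlation). Cell cycle genes rose in 10 of 32 cases (12 adjusted over the list alone), with the replication helicase subunits MCM2 and MCM3 both at 1.44, and the cell cycle phosphatases CDC25A at 1.21 and CDC25C at 1.13 (camera adjusted p = 3.18e-05, adjusted p = 0.631 with an estimated correlation). Epithelial adhesion genes rose in 7 of 19 cases (7 adjusted over the list alone), among them CLDN10 at 2.89 and the splicing regulator ESRP2 at 2.59 (camera adjusted p = 3.43e-06, and 0.0121 with an estimated correlation). Chromatin genes rose in 14 cases without the 3 arrays, and the counts of the other lists here were the same. Another probe set lay at 0.62 for CDC25A and 0.82 for CDC25C. PRDM14, SALL4, KLF4 and TET2 were chosen after their values were seen.

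Of 32 fibroblast matrix genes 26 fell (26 adjusted over the list alone, camera adjusted p = 1.27e-20, and 9.24e-05 with an estimated correlation). They held DCN, a collagen-binding proteoglycan, at −5.66, TGFBI, a matrix adhesion protein, at −5.57, COL1A1 at −3.57 and COL1A2 at −3.30, the chains of type I collagen. Senescence and stress genes fell in 7 of 15 cases (8 adjusted over the list alone), including IGFBP7 at −5.52, the chemokine CCL2 at −4.74 and the cell cycle inhibitor CDKN2A at −4.38 (camera adjusted p = 1.32e-07, adjusted p = 0.0575 with an estimated correlation). Limb and skin position genes fell in 6 of 21 cases (6 adjusted over the list alone), through the transcription factors SHOX2 at −3.51, TBX3 at −3.26, FOXF2 at −3.02 and EMX2 at −2.79 (camera adjusted p = 0.00353, adjusted p = 0.218 with an estimated correlation). Smooth muscle genes fell in 5 of 13 cases (6 adjusted over the list alone), with LMOD1 at −2.18, TPM2 at −1.78, TPM1 at −1.65, MYL9 at −1.58 and TGFB1I1 at −1.46 (the last chosen after its value was seen), while SYNPO2 at −2.49 did not pass (camera adjusted p = 0.000122, adjusted p = 0.455 with an estimated correlation). The brightest other probe set lay at −0.06 for COL1A1, −0.46 for IGFBP7, −0.02 for CDKN2A and −0.27 for SHOX2. With the 3 arrays left out 28 matrix and 7 smooth muscle genes fell, and the counts of the other lists here were the same.

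The other lists did not pass camera between ESCs and teratoma fibroblasts. Among 34 signalling genes 4 rose and 8 fell (5 and 8 adjusted over the list alone), with INHBA, an activin subunit, at −5.53, DKK3 at −4.20 and FGF5 at −3.10, and with rises of ACVR2B (1.66), TCF7L1 (1.24), NODAL (1.08) and FST (1.03). Among 27 MHC and interferon genes 4 rose and 5 fell, with rises of IFITM1 (2.67), GBP2 (1.57), MX1 (1.29) and ISG15 (1.08) and falls of GBP1 (−3.68), IFI35 (−1.97), TAPBP (−1.69), PSMB8 (−1.17) and IFIT3 (−1.09). Among 17 imprinted genes 2 rose and 3 fell, with rises of MAGEL2 (1.82) and SNRPN (1.34) and falls of the growth regulators PLAGL1 (−3.98) and DIRAS3 (−2.70) and of SGCE (−2.02). Of these, ACVR2B, TCF7L1, NODAL, FST, MX1, ISG15, PSMB8, IFIT3, MAGEL2 and SNRPN were chosen after their values were seen. For bone and cartilage, RUNX2 at −4.14 and COL11A1 at −2.76 fell and SPP1 rose by 3.12, out of 11 genes. GATA6 alone fell among 14 endoderm genes, by 3.57, and HOXD10 alone among 26 HOX genes, by 1.08. FABP4 alone rose among 8 adipocyte genes, by 1.77, MLANA among 7 melanocyte genes, by 1.00, and GFAP among 11 neural genes, by 1.14, though another probe set of MLANA lay at −0.06 and of GFAP at −0.94. The brightest other probe set also lay at −0.38 for GBP2, −0.06 for RUNX2, 0.11 for FABP4, −0.15 for TAPBP, −0.77 for GBP1 and −0.70 for FGF5, so these changes hold for the brightest probe set. Of 12 trophoblast genes KRT7 fell by 3.42 and TFAP2A by 2.79, or by 0.58 on another probe set (1 gene adjusted over the list alone). Adjusted over the list alone, the counts of the other lists in these sentences were the same. In limma, 0 genes were called, over all genes or adjusted over the list alone, among 12 early mesoderm genes (3 at an unadjusted p under 0.05), 13 skeletal muscle genes (3), 10 keratinocyte genes (2), 13 macrophage and leukocyte genes (1) and 11 endothelial genes (0). When the 3 arrays were left out 7 signalling genes, 2 adipocyte genes and 1 early mesoderm gene rose, and 6 MHC and interferon, 4 imprinted, 2 neural and 2 skeletal muscle genes fell, with the other counts the same. SRY was the only measured gene of the Y-linked list, with 6.91 ± 0.08 in ESCs and 6.43 ± 0.06 in teratoma fibroblasts, a difference of 0.47 that stayed under the fold limit. Both means pool the male and the female line. With SDs this small, the SRY signal did not set the male line apart from the female line, so it is no guide to sex here.

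**Figure D3:**
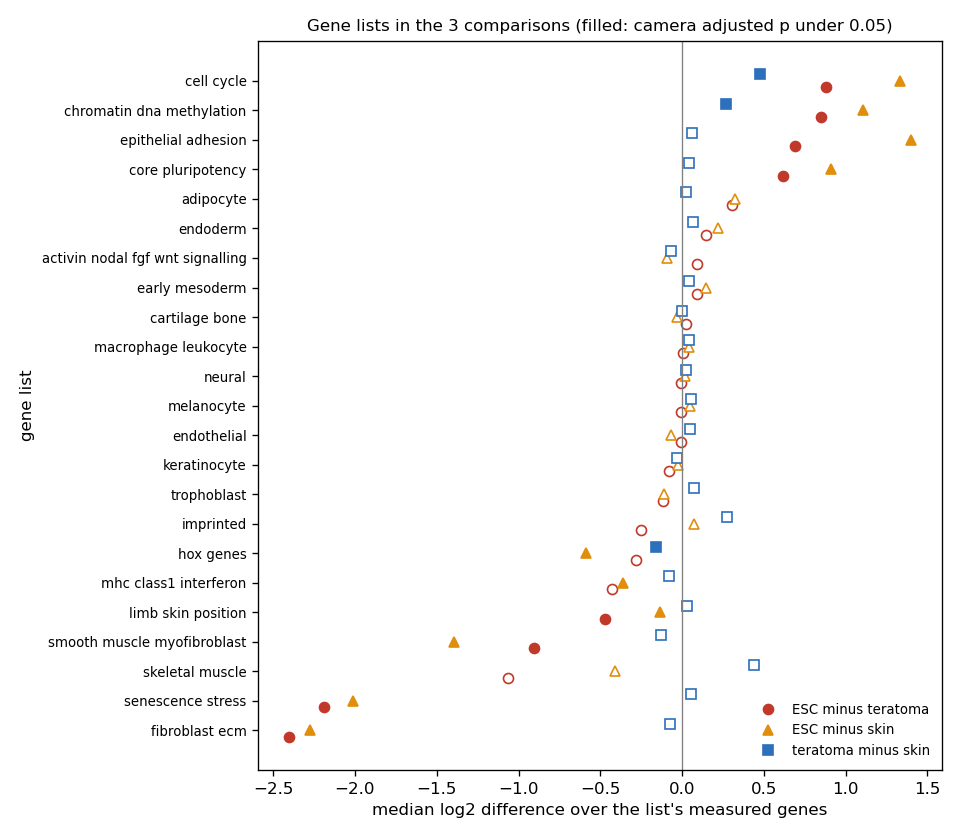
Median log2 difference of the genes of each fixed list in each of the 3 main comparisons. The fibroblast matrix list lay lowest in ESCs, at −2.40 against teratoma fibroblasts and −2.27 against skin.

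Against skin fibroblasts, the comparison asked which genes set ESCs apart from fibroblasts of related adults. POU5F1, EPCAM, NFE2L3, CTSV and LIN28B were again among the largest rises. SOX2 (MmugDNA.27729.1.S1_at, chromosome 2) lay at 11.91 ± 0.89 (n = 2) in ESCs and 4.47 ± 0.12 (n = 3) in skin fibroblasts, and rose by 7.44 (SE 1.5, limma adjusted p = 0.00315). NFE2L3 rose by 6.96, EPCAM by 6.91, POU5F1 by 6.84, CTSV by 6.52, LIN28B by 5.50, DNMT3B by 5.21, and SLAIN1, a microtubule growth protein, by 5.19. ZIC2, a zinc-finger factor of the early neural plate, rose by 5.48 (SE 1.80, adjusted p = 0.0349, the highest of these), and the protocadherin PCDH8 by 5.27. LUM fell by 7.42, KLK8, a secreted protease, by 7.31, FGL2, a fibrinogen-like protein, by 6.96, and NT5E, the fibroblast surface marker CD73, by 6.80. IL6 fell by 6.73, the lipid flippase gene ATP8B3 by 6.66 (adjusted p = 0.0149), FAP by 6.48, IFI16 by 6.36, PRRX1, a mesenchymal transcription factor, by 6.18, and CCDC80 by 6.11. For KLK8 and ATP8B3 another probe set gave a difference of 0.81 and 0.32, so these falls hold for a single probe set. The brightest other probe set lay at 0.72 for LIN28B, −0.84 for NT5E and −0.02 for COL1A1. NANOG again fell by 1.04 (adjusted p = 0.00019). COL1A1 lay at −2.83 and COL1A2 at −3.22, and SRY at 0.44 stayed under the fold limit. In limma, 1061 genes rose and 1125 fell, and without the 3 arrays 1442 and 1380, with EPCAM at 8.34 and LUM at −8.89. The named rises and falls, apart from NANOG, COL1A1, COL1A2 and SRY, came from genes whose ESC means lay outside the range of the 3 skin means.

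Of the fixed lists, 4 rose and 6 fell by camera against skin, and 2 of them also passed with an estimated correlation. Of 32 cell cycle genes 23 rose (23 adjusted over the list alone), led by MCM3 at 2.25, MCM2 at 2.09, TOP2A, which untangles replicated DNA, at 1.94, and GINS2, a replication fork subunit, at 1.86 (camera adjusted p = 1.08e-07, adjusted p = 0.486 with an estimated correlation). Of 31 chromatin genes 17 rose (17 adjusted over the list alone), with TET1 at 4.63, the methyltransferase DNMT3A at 3.64 and CHD7 at 3.38 (camera adjusted p = 2.21e-08, adjusted p = 0.111 with an estimated correlation). Of 20 pluripotency genes 10 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 1.11e-05, adjusted p = 0.124 with an estimated correlation), and of 19 epithelial genes 8 rose (8 adjusted over the list alone, camera adjusted p = 1.78e-06, and 0.0104 with an estimated correlation). Fibroblast matrix genes fell in 27 of 32 cases (27 adjusted over the list alone, camera adjusted p = 1.54e-18, and 0.000139 with an estimated correlation), with DCN at −5.84, and senescence genes in 8 of 15 (8 adjusted over the list alone, camera adjusted p = 2.17e-06, adjusted p = 0.101 with an estimated correlation). Smooth muscle genes fell in 7 of 13 cases (8 adjusted over the list alone), with SYNPO2 at −4.06, or −0.36 on another probe set (camera adjusted p = 4.56e-05, adjusted p = 0.435 with an estimated correlation). HOX genes, which mark position along the body, fell in 4 of 26 cases (4 adjusted over the list alone) through HOXC6 at −4.06, HOXB6 at −2.43, HOXB7 at −2.36 and HOXB5 at −1.71, though other probe sets lay at 0.17, −1.38 and −1.28 for HOXC6 and at 0.09 for HOXB6 (camera adjusted p = 0.00128, adjusted p = 0.486 with an estimated correlation). Limb and skin position genes fell in 6 of 21 cases (6 adjusted over the list alone, camera adjusted p = 0.0310, adjusted p = 0.435 with an estimated correlation). In the MHC and interferon list 4 of 27 rose and 6 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.0426, adjusted p = 0.529 with an estimated correlation), the falls including NLRC5, the activator of MHC class I genes, at −1.30 (chosen after its value was seen), and the rises IFITM1, at 2.66. With the 3 arrays left out 25 cell cycle and 18 chromatin genes rose, and 28 matrix, 9 senescence, 9 smooth muscle, 7 HOX, 7 limb and skin position, 8 MHC and interferon and 4 pluripotency genes fell, with the other counts the same.

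Genes called against both kinds of fibroblast came to 595 higher and 787 lower in ESCs, and to 822 and 994 without the 3 arrays. In limma no gene was called in opposite directions. Independent lists of these sizes would share 48.2 and 73.2 genes. Both comparisons share the ESC sources. Simulations in which no class differed, with all sources given the spread of the fibroblast cultures, gave means of 0.02 and 0 shared genes. Unchanged ESCs leave almost no gene to call, so these counts cannot show the overlap that sharing adds to lists of called genes. Across genes, which are not independent replicates, the log2 differences correlated at 0.924, against 0.686 from shared ESCs without effect, with a covariance of 0.751 against 0.05. With line C3106 set against teratoma fibroblasts and C3806 against skin, 511 genes were higher and 618 lower in both, and with the lines exchanged 361 and 521.

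The chromosome comparison asked whether genes higher in ESCs gather on rhesus 20, 16, 19 and X, the counterparts of the human chromosomes 16 and 17, 19 and X that the series title names. With all arrays X-linked genes made the largest share, but no chromosome passed the test. On X, SLC7A3, an amino acid transporter, rose by 3.58, ARHGAP36 by 2.61, INTS6L by 2.51, ALG13, a glycosylation enzyme, by 2.5, and SOX3, a relative of SOX2, by 2.40 against teratoma fibroblasts. On 16 they were KRT19, an epithelial keratin, at 2.49, RFLNB at 2.45, RDM1, a DNA repair protein, at 2.37, RND2 at 2.27 and PFAS, a purine synthesis enzyme, at 2.11. On 19 they were NTN5 at 2.85, FOXA3 at 2.34, the protease HPN at 2.14, LILRB4 at 2.1 and BST2, an antiviral membrane protein, at 1.89. On 20 they were CLDN6 at 4.87, the kinase PRKCB at 3.21, ESRP2 at 2.59, ZSCAN10, a pluripotency zinc-finger factor, at 2.00, and SNN at 1.84. The brightest other probe set lay at 0.28 for INTS6L, 0.06 for SOX3, 0.66 for LILRB4 and 0.57 for PRKCB. Of 590 X-linked genes 40 were higher in both comparisons, 6.78% against 4.12% of other genes, an odds ratio of 1.69 (95% interval 1.18 to 2.37, Fisher's exact adjusted p = 0.0675). X held 52 genes without the 3 arrays, with an odds ratio of 1.60 (Fisher's exact adjusted p = 0.0612). Chromosome 17 then had the larger share, 10.3% of its genes against 8.81% on X, with an odds ratio of 1.87 (adjusted p = 0.0726). X passed without M088, TA31, TC31, TC38 or TD31 (1.76 to 1.82), and leaving out 1 source or array changed its call in 13 of 52 fits. X also passed with quantile normalisation (1.72), with line ignored (1.86) and with the source as a random block (1.91). Sets matched on expression held 24.9 X-linked genes on average (adjusted p = 0.0966). The odds ratio was 0.97 on 16 (33 genes), 1.01 on 19 (38 genes) and 0.87 on 20 (22 genes), all short of the test. Against teratoma fibroblasts alone, 42 X-linked genes were higher, an odds ratio of 1.64 (adjusted p = 0.0817), which did not pass. Against skin alone, 75 X-linked genes were higher, an odds ratio of 1.84 (1.42 to 2.38, adjusted p = 0.000143), chromosome 17 passed at 1.83 (adjusted p = 0.0404) and 14 passed with fewer genes at 0.67 (adjusted p = 0.0497). Without the fold limit chromosome 19 passed at 1.45. Among genes lower in both, chromosome 9 held more than its share, with an odds ratio of 1.66 (1.19 to 2.26, adjusted p = 0.0224), and 19 held fewer at 0.559 (0.369 to 0.815, adjusted p = 0.0224), as did 20 at 0.522 (0.305 to 0.838, adjusted p = 0.0305). These 3 also passed without the 3 arrays, as did 16 at 0.61. Camera on whole chromosomes called none, and genes that neighbour each other are not independent.

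**Figure D4:**
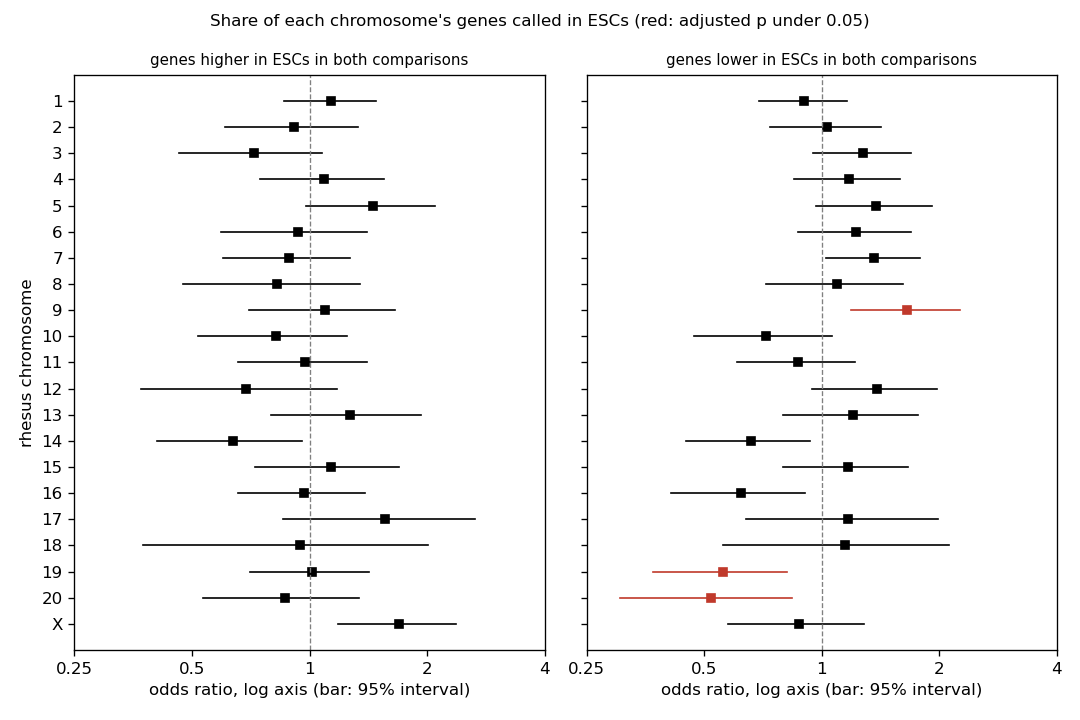
Odds ratio (log axis, with 95% interval) of genes higher and of genes lower in ESCs in both comparisons, for each rhesus chromosome. X lay highest of the 4 named chromosomes among higher genes, at 1.69, and chromosome 9 stood out among lower genes at 1.66.

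Teratoma fibroblasts were compared with skin fibroblasts to see how the 2 differentiated references differ. MEST, a paternally expressed growth gene (MmugDNA.41111.1.S1_at, chromosome 3), lay at 11.82 ± 1.00 (n = 8) in teratoma and 7.06 ± 1.46 (n = 3) in skin fibroblasts, and rose by 4.94 (SE 0.58, limma adjusted p = 0.0215). SOX11, a neural and mesenchymal progenitor factor, rose by 3.69, FBN2, a fibrillin of fetal tissue, by 3.24, ZNF711, an X-linked zinc-finger gene, by 3.08, the protocadherin PCDHB11 by 2.12, and ANXA10 by 2.02. TMSB15A, an actin-binding thymosin on X, rose by 1.97, ST6GALNAC3 by 1.86, and IQCG and PTPRD by 1.84 each. FAM180A (MmunewRS.923.1.S1_at, chromosome 3) lay at 4.63 ± 0.52 in teratoma and 8.82 ± 1.87 in skin fibroblasts, and fell by 4.25 (SE 0.63, adjusted p = 0.0243). C1QTNF5 fell by 2.92, MOXD1 by 2.75, ISM1 by 2.45, KCNJ8, a potassium channel of mural cells, by 2.38, HOXB7 by 2.20, HOXB6 by 2.03, CAB39L by 2.00, HYAL1, which degrades hyaluronan, by 1.80, and CTBS by 1.76. Another probe set lay at 0.05 for HOXB6, 0.13 for FBN2, −0.26 for ISM1 and 0.70 for ZNF711. The naming rule took only genes whose teratoma means lay outside the range of the skin means. In limma the adjusted p of these genes was 0.0423 at most, for IQCG and PTPRD. MEST lay at 5.77 and FAM180A at −4.88 without the 3 arrays.

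POU5F1 (0.05), NANOG (0.01), COL1A2 (0.07), COL1A1 (0.74), DNMT3B (0.64) and SRY (−0.03) were not called between teratoma and skin fibroblasts, nor was SOX2 at 3.68 (SE 1.12, limma adjusted p = 0.135). In limma, 33 genes rose and 19 fell (2557 at an unadjusted p under 0.05), and without the 3 arrays 93 and 77. Single sources moved the count of higher genes, to 1 without M088 or TB38, 2 without M032 or TC38 and 67 without TE31. By camera the cell cycle list lay higher (median 0.48, adjusted p = 5.18e-09, adjusted p = 0.740 with an estimated correlation) with 0 of 32 genes called, over all genes or adjusted over the list alone (16 at an unadjusted p under 0.05). The chromatin list lay higher too (adjusted p = 0.00025, adjusted p = 0.740 with an estimated correlation), with DNMT3A called at 1.11, or 0.55 on another probe set (2 adjusted over the list alone), and HOX genes lay lower (adjusted p = 0.00075, adjusted p = 0.740 with an estimated correlation), with HOXB6 and HOXB7 called (4 adjusted over the list alone). MEST was the only imprinted gene called (1 adjusted over the list alone). The 19 other tested lists held no called gene over all genes, fibroblast matrix genes among them (0 of 32, 5 at an unadjusted p under 0.05), and adjusted over the list alone 1 neural gene rose and 1 fell. With the 3 arrays left out 2 chromatin, 1 signalling, 1 pluripotency, 1 fibroblast matrix and 1 leukocyte gene were higher, 4 HOX, 1 MHC and interferon and 1 neural gene were lower, and the smooth muscle list passed too (camera adjusted p = 0.0226, adjusted p = 0.881 with an estimated correlation).

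**Figure D5:**
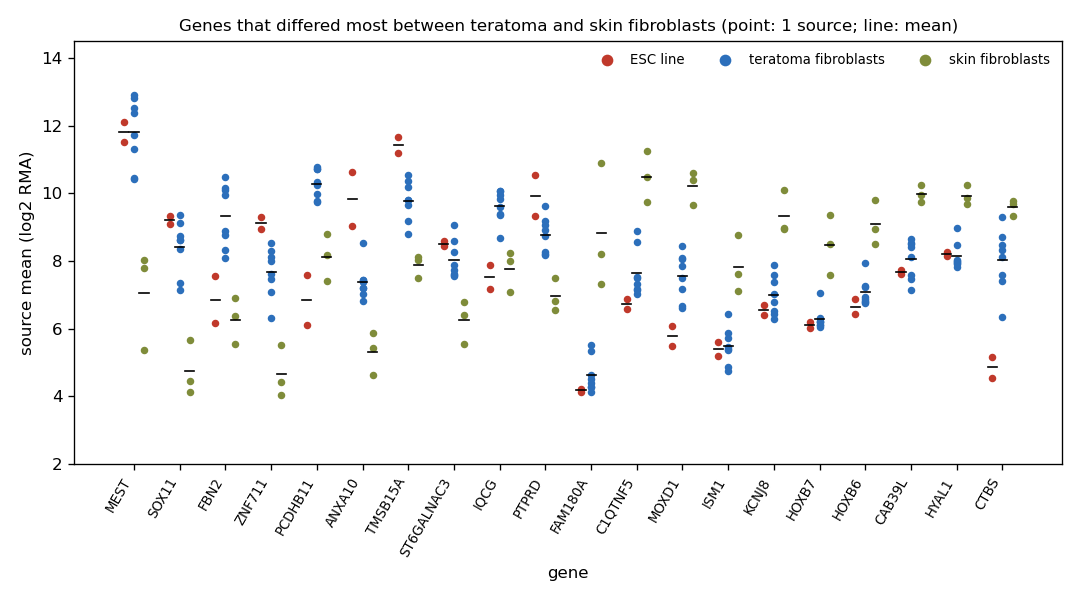
Source means (log2) of the genes that differed most between teratoma and skin fibroblasts, each point a source, with ESCs beside them and lines at the means. MEST had means of 11.82 in teratoma and 7.06 in skin fibroblasts.

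The ESC lines were compared because they differ in sex. GATA6, an endoderm factor, was higher in C3806 by 3.53 (adjusted p = 0.00875, n = 3 arrays each, limma), LGR5, a WNT pathway receptor (MmugDNA.40626.1.S1_at, chromosome 11), by 3.44, DKK1 by 3.31, NR2F2, a mesenchymal nuclear receptor, by 2.90, and PLAC9 by 2.67. Lower in C3806 were SPP1, a secreted phosphoprotein, by −3.17, KCTD8 by −2.44, SPCS2 by −2.23, the tight-junction receptor CXADR by −2.06, and PPP2R2C by −2.01. Another probe set lay at 0.41 for LGR5, 0.36 for PLAC9, −0.50 for CXADR and −0.36 for PPP2R2C. In limma, 55 genes were higher and 87 lower in C3806. Simulated sources that differed only by the spread seen among fibroblast cultures gave 365 calls. Whether ESC lines vary as much as fibroblast cultures cannot be told with 1 source per line. Single arrays moved the counts, to 381 and 256 without C3806a, 442 and 294 without C3806b, and 26 and 42 without C3106b. Without the 3 arrays the counts were 46 and 107, and GATA6 lay at 2.46, LGR5 at 2.37, DKK1 at 1.09, NR2F2 at 0.96, PLAC9 at 0.94 and SPP1 at −1.80. The named genes higher in C3806 were high in fibroblasts, and its mean holds the array labelled C3806c. Each line is a single source, so the test describes these cultures and not the sexes.

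Between teratoma fibroblasts of the lines, 4 genes were higher and 2 lower in the female line's 3 cultures than in the male line's 5. SPMAP2, a sperm gene, differed by 3.13 (SE 0.08, limma adjusted p = 5.15e-08), RIT2, a neural GTPase, by 3.41, the receptor PTH2R by 2.62 and the hair keratin KRT81 by 2.27, while ZNF534 lay at −1.30 and AMACR, which handles branched fatty acids, at −1.13. For these genes the adjusted p was 0.0216 at most. Without the 3 arrays, 5 genes were higher and 1 lower. Single cultures moved the counts, to 1 higher and 0 lower without TB38 or TE31, and 2 and 0 without TA38. The difference between ESCs and teratoma fibroblasts itself differed between the lines for 48 genes in limma (12 higher and 36 lower in line C3806). LGR5 led at 4.39 (SE 0.46, adjusted p = 0.00223), followed by LUM at 3.46, IFI16 at 2.79, ARID5B at 2.44 and ALDH1L2 at 2.34, and lowest were CTSV at −2.91, KCTD8 and POU5F1 at −2.79, SPCS2 at −2.56 and EPCAM at −2.53. Another probe set lay at 1.23 for LGR5, 0.66 for ALDH1L2 and −0.18 for ARID5B. Each ESC line is 1 source, so this test cannot tell a line difference from a difference between ESC cultures. With all arrays and the source as a random block, 0 genes were higher and 2 lower. Without the 3 arrays 3 were higher and 5 lower, and POU5F1 lay at −0.11, LUM at 0.54, LGR5 at 3.30 and EPCAM at 0.32.

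The teratoma cultures of a line were compared to see how much cultures from different teratomas differ. Skeletal muscle and HOX genes were among those that differed widely. MYH3, the embryonic muscle myosin, had a mean of 11.80 in TD31 and 10.47 in TB31 but 4.44 in TA31 and 4.51 in TE31 (limma F test on arrays, adjusted p = 1.52e-07). MYL1, a muscle myosin light chain, lay at 10.92 in TD31 and 8.61 in TB31, and MYF5, a muscle-determining factor, at 9.46 and 6.87. Without the array labelled TB31c, TB31 lay at 12.18 for MYH3, above TD31, at 10.96 for MYL1 and at 8.40 for MYF5. Of 13 skeletal muscle genes 8 lay at least 2-fold above every skin culture in TB31, 8 in TD31, 5 in TA38, 5 in TB38 and 1 in TC31. The counts were 9 in TB31, 8 in TD31, 6 in TA38, 6 in TB38, 3 in TC31, 2 in TC38 and 1 in TA31 without the 3 arrays. SOX2 lay at 10.33 in TA31 and 4.75 in TB31, and PAX6, a neural and eye factor, at 10.29 and 5.19. The position gene HOXA9 lay at 9.93 in TE31 and 4.28 in TD31 (adjusted p = 2.82e-09), and the desmosome protein gene DSP at 12.84 in TD31 and 4.12 in TE31 (adjusted p = 1.31e-06). H19, an imprinted RNA, ranged over 3.78 log2 units among these cultures and over 4.88 among skin cultures. In all, 1234 genes differed by at least 2-fold among the 5 teratoma cultures of the male line, 466 among the 3 of the female line and 747 among the 3 skin cultures. Without the 3 arrays the counts were 1637, 720 and 1239. Of 13 skeletal muscle genes 10 differed among the male line's cultures, 2 among the female line's and 2 among skin cultures (10, 5 and 3 without the 3 arrays). Of 26 HOX genes the counts were 10, 6 and 9 (10, 6 and 7 without the 3 arrays), so HOX genes differed among skin cultures too. No test of enrichment was run for the lists here. The tests rest on arrays of a culture, and these genes were taken from the lists after their values were seen.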

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

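The tests of the out-of-place arrays, of single cultures without the 3 arrays, of X-linked genes and of SOX2 and PAX6 were chosen after the result was seen, and the counts over other splits of the samples were planned.

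Among the 8 teratoma cultures, 1 culture stood apart for 21 of the 221 named genes (9.5%), by the gap to its nearest neighbour as a share of the whole range. Chance picks about 1 in 20 groups, and 7.9% of all genes did so. TA31 stood apart for BEND4 (0.87), PCDH8 (0.68) and ANXA10 (0.64), TA38 for DCN (0.63), MIXL1 (0.61) and ACTG2 (0.59), and TB38 for ARHGAP36 (0.65). TB31 stood apart for the position genes HOXB7 (0.73) and HOXB6 (0.57), and TC31 for the endoderm factors SOX17 (0.68) and FOXA1 (0.57) and for HAND1 (0.65). TD31 stood apart for GATA6 (0.7), DKK1 (0.6) and DSC3 (0.56). TE31 stood apart for the neural gene STMN2 (0.71), ITGAM (0.64), COL11A1 (0.56), HPN (0.55), TET3 (0.55) and DPPA4 (0.54). STMN2 lay at 8.69 in TE31 and between 6.25 and 6.96 in the other cultures. The share of the range does not measure size: MIXL1 lay at 6.02 in TA38 and between 6.15 and 6.22 in the others. Differences in TE31 were also small for HPN (5.66 against 5.28 to 5.45), DPPA4 (6.01 against 5.7 to 5.84) and ITGAM (6.05 against 5.65 to 5.79). TB31 no longer stood apart without the 3 arrays for HOXB7 (0.16 at most for any culture) or HOXB6 (0.07), so these rest on the array labelled TB31c, whose profile lies nearest to skin culture M106p1. The ratio also fell below the critical value for ANXA10 (0.5), DPPA4 (0.38) and MIXL1 (0.33), and 16 of the 21 genes still passed. The cause of the other single-culture differences was not tested.

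For 18 named genes, limma's interaction test found that the difference between ESCs and teratoma fibroblasts was not the same in both lines. In the female line less the male line, it was higher for LGR5 (4.39), LUM (3.46), IFI16 (2.79), ARID5B (2.44), ALDH1L2 (2.34) and COL1A2 (1.4). It was lower for CTSV (−2.91), KCTD8 (−2.79), POU5F1 (−2.79), SPCS2 (−2.56), EPCAM (−2.53), DPPA4 (−2.32), LIN28B (−2.29), NELL2 (−2.07), CHGB (−1.83), CLDN6 (−1.58), SOX3 (−1.46) and ESRP2 (−1.23). Without the 3 arrays the adjusted p in limma was 0.0516 or more for each of these genes. Of the 18 genes 15 then differed by less than 2-fold, among them POU5F1, LIN28B and LUM at −0.11, −0.07 and 0.54, so these 15 calls rest on the 3 arrays. LGR5 (3.30), SPCS2 (−1.66) and KCTD8 (−1.42) kept a larger difference and missed the threshold. Each ESC line is 1 source and the spread behind the test comes from fibroblast cultures. The test therefore cannot tell a line difference from a difference between ESC cultures.

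The pattern of the 3 arrays was weighed next. The array labelled C3806c lay nearest to TC38, M106p1f to TD31 and TB31c to skin culture M106p1. A swap between 2 of the arrays would leave each in the other's source, and 0 such pairs were found. A mixture of the labelled cells with the other cells would keep the labelled source's genes above background, but these genes showed a median share of the labelled source of 1.8% at most. A wrong label stays open as a hypothesis: 3 of the 3 arrays correlated with the other source as well as its own arrays did with each other, at 0.9954, 0.9961 and 0.9929 or above. No biological explanation was tested, since the design gives none for a single array.

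X-linked genes among the genes higher in ESCs came to 40, a share that did not pass its test. Sets matched on expression held 24.9 X-linked genes on average. The p from these sets was 0.0046 unadjusted and 0.0966 adjusted over the chromosomes. Fisher's exact test without matching gave 0.0032 unadjusted and 0.0675 adjusted, so matching on expression changed little. These values argue against expression level of the called genes as the source of the share on X. Whether X holds more than its share at all is not settled after adjustment. The female line alone stays open as an explanation: the odds ratio was 1.38 (0.991 to 1.87) in the male line and 1.82 (1.11 to 2.84) in the female line. These intervals overlap. Without the 3 arrays the values were 1.38 (0.974 to 1.91) in the male line and 1.33 (0.938 to 1.84) in the female line. The higher value of the female line thus rests on the 3 arrays, and the lines cannot be told apart on X. The share on X may also belong to ESCs of both sexes, which a single line per sex cannot show.

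SOX2 and PAX6 were high in some teratoma cultures: SOX2 lay at least 4-fold above every skin culture in 5 of the 8. ESCs left in the teratoma cultures were argued against, since POU5F1 was 4.9 at most there, while the ESC share that SOX2 implies would give 8.32 or more. Neurons or glia in the teratoma cultures stay open: at most 1 of the other 10 neural genes lay 2-fold above skin in any of these cultures, but 5 of the 10 lay above the median signal in skin, which would hide a small share. Other cell types that make SOX2 and PAX6, such as neural or eye progenitors, may stay as a source and were not tested, nor was RNA of the mouse host. The 2 weaker SOX2 probe sets showed smaller differences between teratoma and skin fibroblasts (0.6 and 0.31, against 3.68).

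Other splits of the samples gave fewer calls than the real ones in most comparisons. Between ESCs and teratoma fibroblasts 1 of 24 splits gave 1562 calls or more, the real one, with 11 in the highest other split, which argues against chance. The smallest share that 24 splits can give is 1 of 24. Every other split also puts an ESC line among the teratoma cultures, which widens the spread behind the test and lowers its count. For genes called against both fibroblast kinds it was 1 of 24 (1382, highest other 7), on the same splits and with the same limits. Between ESCs and skin the 10 splits are too few for a share under 0.05 (2186, highest other 16). Between teratoma and skin fibroblasts 1 of 100 drawn splits of the 165 gave 52 calls, the real one, and the highest other gave 28. Without M088 1 gene was higher and 0 lower, and without TB38 1 and 1, so chance is argued against only weakly. For the lists, 41 of 100 splits gave the 3 or more that passed camera (highest other 6), so chance cannot be excluded. Between teratoma fibroblasts of the lines 2 of 56 splits gave as many as 6 genes, a share under 0.05, but 1 of them was not the real one, and without TB38 or TE31 1 gene was higher and 0 lower, so chance is argued against only weakly. Between the ESC lines the 10 splits are too few (142, highest other 374), and 5 of 10 gave as many genes, so a line difference and chance cannot be told apart. For differences among cultures 1 of 100 splits gave as many genes for the male line (1234, highest other 555), the female line (466, highest other 260) and skin (747, highest other 478), which argues against chance in each.

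Probe sets with no gene name held signals that no named comparison uses. In both comparisons 876 of the 26716 unnamed probe sets were higher in ESCs and 733 lower, 3.28% and 2.74%, against 4.21% and 5.57% of named genes. Of 674 viral probe sets limma called 0 (60 against teratoma and 52 against skin fibroblasts at an unadjusted p under 0.05).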

How the results depend on the processing

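The results without 3 arrays, without C3806a, without all of these and with no replicate letter were added after the data were seen, and the other alternatives were planned. Of 415 counts and tests under alternatives, 302 kept their side of the threshold and stayed within 1.5 times. Of 3665 values of named genes, 3323 kept their direction and call, 125 lost a call, 202 gained one and 15 reversed. Unless a reason is given, the cause was not tested.

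With all arrays and the source as a random block, teratoma against skin gave 165 higher and 134 lower (33 and 19 in the main result), the teratoma lines 19 and 14 (4 and 2), and the interaction 0 and 2 (12 and 36). The X odds ratio was 1.91 and passed, so that 1 chromosome passed for higher and 5 for lower genes (0 and 3 in the main result). With arrays as independent samples the counts were 223 and 168, 31 and 27, and 28 and 58, with X at 1.96 and 1 chromosome past. Taking arrays for sources raises the number of samples without adding cultures.

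The arrays of sources share replicate letters. Over 199 pairs of same-lettered arrays from different sources the deviations correlated at a median of 0.0367 (−0.725 to 0.598), 37.2% above 0.1, against −0.0199 for other letters, and 11 of 39 arrays had their best partner under their own letter, so the letters did not pair the samples. With the replicate letter as a block beside the sources, teratoma against skin gave 338 and 275, the teratoma lines 54 and 65, and the interaction 207 and 212, with X at 1.97 and 1 chromosome past. The same fit with no letter gave 252 and 186, 50 and 62, and 154 and 151, with X at 1.95 and 1 past, so most of the rise comes from taking arrays for sources.

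With line ignored X was 1.86 and 1 chromosome passed, and with quantile normalisation X was 1.72 and 1 passed. Median centring gave 30 lower genes in teratoma against skin (19 in the main result), beside 35 higher. The other scalings moved the median of all genes by less than 0.1 in the main comparisons, to 0.055 or 0.079 at most against teratoma fibroblasts.

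On the brightest other probe set of a gene the sign reversed for KLK8 (0.81), ATP8B3 (0.32), HOXB6 (0.09), HOXC6 (0.17, with 2 dimmer probe sets at −1.38 and −1.28), GBP2 (−0.61), CDKN2A (0.01), MLANA (−0.09) and LEP (−1.81) in ESCs against skin, for MLANA (−0.06) and GFAP (−0.94) against teratoma fibroblasts, for HOXB6 in teratoma against skin (0.05) and for ARID5B in the interaction (−0.18). With all probe sets the interaction gave 81 lower, the ESC lines 237 lower, and 6 chromosomes passed for lower genes.

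Without the dimmest 25% of genes the interaction gave 3 and 3 and the ESC lines 56 lower. Without the dimmer 50%, ESCs against teratoma gave 279 higher, against skin 584 higher, both 252 higher, the teratoma lines 1 and 1, the interaction 3 and 0, the ESC lines 31 lower, cultures of the male line 712, of the female line 268 and skin cultures 434, with 1 chromosome past for lower genes. Fewer genes were tested in these. Dimness was judged by the mean over all arrays, 24 of teratoma fibroblasts, 9 of skin fibroblasts and 6 of ESCs. Genes expressed mainly in ESCs are therefore more easily left out as dim. The counts of genes lower in ESCs than in fibroblasts stayed within 1.5 times their main values.

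With no fold limit, ESCs against teratoma gave 2815 and 2069, against skin 3137 and 2256, both 2508 and 1752, teratoma against skin 70 and 49, the ESC lines 235 and 276, and cultures 2861, 1478 and 2037. Chromosome 19 rose to 1.45 and passed, and 2 chromosomes passed for higher and 1 for lower genes. At an adjusted p under 0.01, teratoma against skin gave 1 and 1, the teratoma lines 1 and 0, the interaction 3 and 22, and the ESC lines 11 and 31.

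With an estimated correlation camera passed 1 list up and 1 down against teratoma fibroblasts and 1 and 1 against skin, the epithelial and fibroblast matrix lists, and 0 and 0 in teratoma against skin. With fry 8 lists rose against skin, and 0 and 0 passed in teratoma against skin. Against teratoma fibroblasts alone 6 chromosomes passed for lower genes, and against skin alone X was 1.84 and 3 passed for higher genes.

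Without the 3 arrays, teratoma against skin gave 93 and 77 with 2 lists down, the teratoma lines 1 lower, the interaction 3 and 5, cultures of the female line 720 and skin cultures 1239, and EPCAM reversed in the interaction at 0.32. Without C3806a the interaction gave 78 and 91 and the ESC lines 381 and 256. Without all 4, teratoma against skin gave 93 and 77 with 2 lists down, the teratoma lines 1 lower, the interaction 16 lower, the ESC lines 101 and 146, and cultures 727 and 1247, with POU5F1 at 0.05 and EPCAM at 0.36 in the interaction.

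Each source and each array was left out in turn, and comparisons that need a left-out ESC source were not made for it. ESCs against teratoma ranged from 388 to 937 higher and 575 to 1168 lower, against skin from 718 to 1349 and 790 to 1354, and both from 364 to 876 and 502 to 1021, each lowest without C3106 and highest without C3806c. Teratoma against skin ranged from 1 to 67 higher and 0 to 62 lower: higher and lower counts were 2 and 2 without M032, 1 and 0 without M088, 1 and 1 without TB38, 2 and 1 without TC38, and 67 and 46 without TE31. They were 14 higher without TC31, 15 higher without TD31 and 50 lower without M106p1. Without a single array they were 1 and 1 (M106p1b), 2 and 1 (M106p1e), 67 and 62 (M106p1f), and 1 and 0 (TB31a and TB31b alike). The ESC lines ranged from 26 to 442 higher and 42 to 294 lower (26 and 42 without C3106b, 381 and 256 without C3806a, 442 and 294 without C3806b). The interaction ranged from 4 to 96 and 5 to 107 (4 and 5 without C3806c, 78 and 91 without C3806a, 96 and 107 without C3806b, and 5, 6 and 5 higher without TB31, TB38 and TC31). The teratoma lines ranged from 1 to 4 and 0 to 3, with 1 higher without TB38 or TE31 and 2 without TA38, 0 lower without TA38, TB38, TC31, TD31 or TE31, and 1 lower without TA31, TC38 or the array M106p1f. Cultures of the male line ranged from 1095 to 1443, of the female line from 378 to 593, and skin cultures from 644 to 1086.

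The X odds ratio ranged from 1.47 to 1.82 and passed without M088 (1.80), TA31 (1.81), TC31 (1.78), TC38 (1.82) or TD31 (1.76), and without the arrays TA38a, TA38c, TB31a, TB31b, TB38a, TC31c, TC38a or TE31b (1.73 to 1.78). Chromosome 16 ranged from 0.81 to 1.27, 19 from 0.9 to 1.49 and 20 from 0.74 to 1.01. Chromosomes past the test ranged from 0 to 2 for higher genes, with 2 without TD31 and 1 in the other cases named here for X, and from 2 to 6 for lower genes, with 6 without M106p1, and 5 without TA38, TC38 or the arrays C3106d, M032b, M106p1e, M106p1f or TC31b. Lists past camera ranged from 4 to 5 up and 4 to 5 down against teratoma fibroblasts, 4 to 5 up and 4 to 6 down against skin, and 2 to 3 up and 1 to 2 down in teratoma against skin, where 2 were down without M032, M106p1, TB31 or TE31. Of 4907 values of named genes 4649 kept their call, 228 lost it, 30 gained one and 0 reversed.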

Other observations

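The values here were chosen after the data were seen. The array labelled C3806a had a 3′ to 5′ gap of 1.42 in GAPDH probe sets against at most 0.92 in the other arrays. NANOG lay lower in ESCs than in both fibroblast kinds, at 8.63 against 9.67 and 9.66, on its only probe set, so whether that probe set reads NANOG mRNA in these cells stays unsettled. Among cultures of the male line, the imprinted genes H19 and DLK1 were lowest in TE31 and highest in TD31, with H19 at 9.67 and 13.45 (limma adjusted p = 5.05e-05) and DLK1 at 6.66 and 11.08 (adjusted p = 0.000109). Without the array labelled TB31c, H19 was highest in TB31, at 13.58.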
